A study of Mus musculus with 6 samples.

How the data were processed

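Total RNA came from mouse cortical neurons at day 14 in culture, seeded at 500000 neurons per well and given lentivirus at a multiplicity of infection of 5, per the labels' protocols. Biotin-labelled cRNA was made from 500 ng of RNA and read on an Illumina bead array. The deposited table holds 1 intensity per probe and array without normalisation between arrays, per the file headers. Its values are positive with a floor near 50 and array means that differ, so they were taken as not background-subtracted. The scanner software and its background setting are not given in the sources used here. Beside each intensity the deposited table gives a detection p-value, per the file headers. A second deposited table holds intensity values that share the same distribution on all 6 arrays. These differed from quantile-normalised deposited intensities by at most 0.00462 on the log2 scale, and served as an alternative only.

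Groups and replicate numbers were taken from the sample labels. Background was corrected by the normexp model of limma 3.58.1 (neqc) from the detection p-values, with an offset of 16, followed by quantile normalisation and log2, in R 4.3.3. Of 45281 probes, 18627 had a detection p under 0.05 on at least 3 arrays. Gene names came from the probe annotation and were brought up to date with a RefSeq table of assembly GRCm38.p6, used for names alone, which updated the symbol of 1424 probes. In all 35784 probes had a gene symbol and 9497 had none. Each gene was represented by its detected probe with the highest mean over the 6 arrays, giving 11183 genes. Other detected probes are given for some named genes, and where none is given the probes may still differ in size or call. No coordinates are given, since the files name no genome build.

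Differences are miR-27b knockdown minus control on the log2 scale, from a linear model with moderated variance (limma lmFit and eBayes) on all 6 arrays. They come with standard errors and p-values adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A gene undetected on all arrays of a group has a lower bound on its fold, computed against the dimmest detected probe of each of those arrays or the gene's own value if higher. Sizes of dim genes depend on the background correction, and without it 22 of the 96 named genes past the threshold had folds over 1.5 times smaller. Gene lists were tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over 21 lists. These covered presynaptic, postsynaptic, voltage-gated channel and activity-induced genes, markers of 7 kinds of cell (excitatory and inhibitory neurons, astrocytes, oligodendrocyte lineage, microglia, vascular cells and fibroblasts, progenitors), axon growth, Polycomb complexes, reported miR-27 targets, small RNA machinery, interferon, p53, endoplasmic reticulum stress, cholesterol, oxidative phosphorylation and ribosome genes. No list call held with an estimated correlation, where the lowest adjusted p was 0.418. The adjustment gave that same value to most lists, so it does not rank them. Before adjustment, the camera p of the lists otherwise called ran from 0.0483 (postsynaptic) to 0.274 (ribosome). It was 0.0774 for oxidative phosphorylation and 0.0915 for presynaptic genes. The lists come from general knowledge and not from these samples. The excitatory neuron list shares 3 genes with other lists and the inhibitory neuron list 2.

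The tests, lists and alternatives were chosen before the data were examined, as was the rule for named genes. Exceptions, chosen after values had been seen, are the tests so described with the patterns below, the lists of early and late neuronal genes and the settings tried for them. That rule took the 12 genes per direction with the largest absolute difference among those past the threshold with the same sign in all 3 preparations, leaving out clone identifiers. It added up to 4 members per list past the threshold with the largest difference, or the 2 with the smallest p where none passed, and Bmi1, Dicer1 and the host gene of miR-27b.

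The series describes 3 neuronal preparations, and arrays with the same number deviated together from their group means, with correlations of 0.148, 0.256 and 0.249 across genes. The numbers were therefore taken as pairs, and a fit with preparation as a block was run beside each result. Alternatives covered background correction, normalisation, starting values, filters, pairing, the variance model, array weights, choice of probe, set test and leaving out each array or pair. A test of genes with miR-27 seed sites was not run, since no transcript sequences were held. In simulated data for this comparison, 200 of 11183 genes were changed by 1 or 0.5 on the log2 scale. A small further set was changed by less. The fit recovered 89% of genes changed by 1 and 23% of those changed by 0.5. Of its calls, 6.61% were unchanged genes. In the data 32% of genes passed, far more than were changed in the simulation, so these shares may not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. MicroRNA levels, protein levels and cell counts were not analysed here.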

Results

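Messenger RNA was measured in mouse cortical neurons kept in culture for 14 days. The neurons came from C57BL/6J mice with floxed Dicer alleles, and the series describes 3 separate neuronal preparations. Neurons were given a control lentivirus or a lentivirus that lowers the microRNA miR-27b. Each group held 3 arrays, 6 in all. Arrays of the same number were taken as pairs from 1 preparation, an inference from the replicate numbers and from deviations that ran together. Probes called present at a detection p under 0.05 numbered 17498 to 19163 per array, or 38.6% to 42.3% of the 45281 probes. Mean intensity per array lay between 669 and 788. Spearman correlations between arrays ran from 0.876 to 0.907 across probes, which are not independent replicates, and knockdown replicate 3 correlated least with the others, at 0.876 to 0.886. The first principal component held 65.7% of the variance and separated the groups, and the next held 14.1%. The number of arrays limits the precision of every value given here.

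The design asks which transcripts differ when miR-27b is lowered. No probe for miR-27b is named on the array, so its level in these cells was not measured and the knockdown could not be checked from these data. Bmi1, a Polycomb repressive complex 1 gene that the study is known to treat as a miR-27b target, had log2 intensities of 7.73, 7.24 and 7.56 in controls. The same-numbered knockdown arrays read 8.08, 7.64 and 8.06. The difference of 0.42 (SE 0.17, n = 3 per group; higher in 3 of 3 pairs) did not pass, with a limma adjusted p of 0.113. With preparation as a replicate block the same difference had an adjusted p of 0.0194. A two-sided exact permutation test of the 3 against 3 values, which ignored the pairs, gave p = 0.2. The smallest p that this test can reach is 0.1. Dicer1, the gene of the enzyme that cuts microRNA precursors, differed by 0.64 (SE 0.21, adjusted p = 0.0626, or 0.0314 without background correction), and its other detected probe by 0.17. Aopep, the host gene of miR-27b, differed by -0.59 (SE 0.26) with an adjusted p of 0.133, or 0.0251 with the replicate block.

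Gene expression differed widely between the groups. Of 11183 genes tested, 1868 were higher and 1712 lower after miR-27b knockdown, together 32.0% of the genes. Each of these 3580 moved the same way in all 3 preparations. The same arrays selected these genes, and passing with so few arrays nearly requires a shared sign. The shared sign is therefore not separate evidence for the calls. At least 2-fold differences were found for 299 of the higher and 297 of the lower genes, or 148 and 167 without background correction. The balance of directions depended on the scaling of the arrays. With cyclic loess it was close to that of quantile normalisation, at 1846 genes higher and 1776 lower. With median scaling in place of quantile normalisation, 914 genes were higher and 1360 lower, so that 40.2% of the calls were higher, against 52.2%. Leaving out control replicate 1 also lowered the counts by over 1.5 times, to 1242 higher and 1050 lower.

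The gene with the largest rise was Trib3, a pseudokinase gene induced by the integrated stress response, at 3.27 (SE 0.53, adjusted p = 0.00538), or 2.37 without background correction. It was detected on 2 of 3 control arrays. Draxin, an axon guidance protein gene detected on 1 of 3 control arrays, rose by 2.89 (SE 0.21, adjusted p = 0.000455), the secretin hormone gene Sct by 2.68 (SE 0.19, adjusted p = 0.000389), and the galanin neuropeptide gene Gal by 2.56 (SE 0.13, adjusted p = 0.000229). Gal was detected on no control array, and was at least 4.57-fold higher after knockdown. The same held for Spink2, a serine protease inhibitor gene (at least 5.45-fold), Adgre1, which encodes the macrophage antigen F4/80 (at least 3.55-fold), Adh7, an alcohol dehydrogenase gene (at least 3.41-fold), and Chrna3, a nicotinic acetylcholine receptor subunit gene (at least 3.20-fold). These bounds rest on the background correction, and without it they were 2.54 for Gal, 2.93 for Spink2, 2.11 for Adgre1, 2.05 for Adh7 and 1.96 for Chrna3. The other detected probe of Adgre1 rose by 1.56 (limma adjusted p = 0.00377), against 2.43 for the probe used. The remaining genes with the largest rises were the mitochondrial arginase gene Arg2 at 2.65, Tmem200b at 2.42, the glypican gene Gpc2 at 2.39 and the serine protease gene Klk8 (neuropsin) at 2.29, with adjusted p of at most 0.00487. Without background correction Draxin rose by 1.87, Sct by 1.93 and Arg2 by 1.74, and Gpc2 rose by 1.58 with normexp correction at an offset of 50.

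Iqgap2, a scaffold protein gene of the actin cytoskeleton, had the largest fall, at -2.80 (SE 0.15, adjusted p = 0.000229), and was detected on 1 of 3 knockdown arrays. Without background correction it differed by -1.74, and Rasgrp1 had the largest fall, at -2.29. The plasma membrane zinc exporter gene Slc30a1 differed by -2.46 (SE 0.15, adjusted p = 0.000312), and the desmosomal plakophilin gene Pkp2 by -2.42 (SE 0.18, adjusted p = 0.000456). The activity-induced genes Arc and Egr4 differed by -2.39 and -2.30, and Rasgrp1, which encodes an activator of Ras, by -2.38 (SE 0.20, adjusted p = 0.000563). The other genes of this group were the lectin gene Mlec at -2.28, the signal peptidase subunit gene Spcs3 at -2.19, Tmem64 at -2.21, Crhbp, which encodes the corticotropin-releasing hormone binding protein, at -2.18, the membrane oestrogen receptor gene Gper1 at -2.16, and Unc80, a subunit gene of the sodium leak channel, at -2.12. Their adjusted p were at most 0.0035. Without background correction Slc30a1, Pkp2, Arc and Mlec differed by -1.66, -1.70, -1.80 and -1.68, Gper1 by -1.29 and Unc80 by -1.49. Other detected probes differed by -1.94 for Iqgap2, -1.80 and -1.46 for Pkp2, -2.31 for Rasgrp1 and -1.37 for Spcs3. Those of Mlec differed by -2.22, -2.39 and -1.19.

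**Figure D1:**
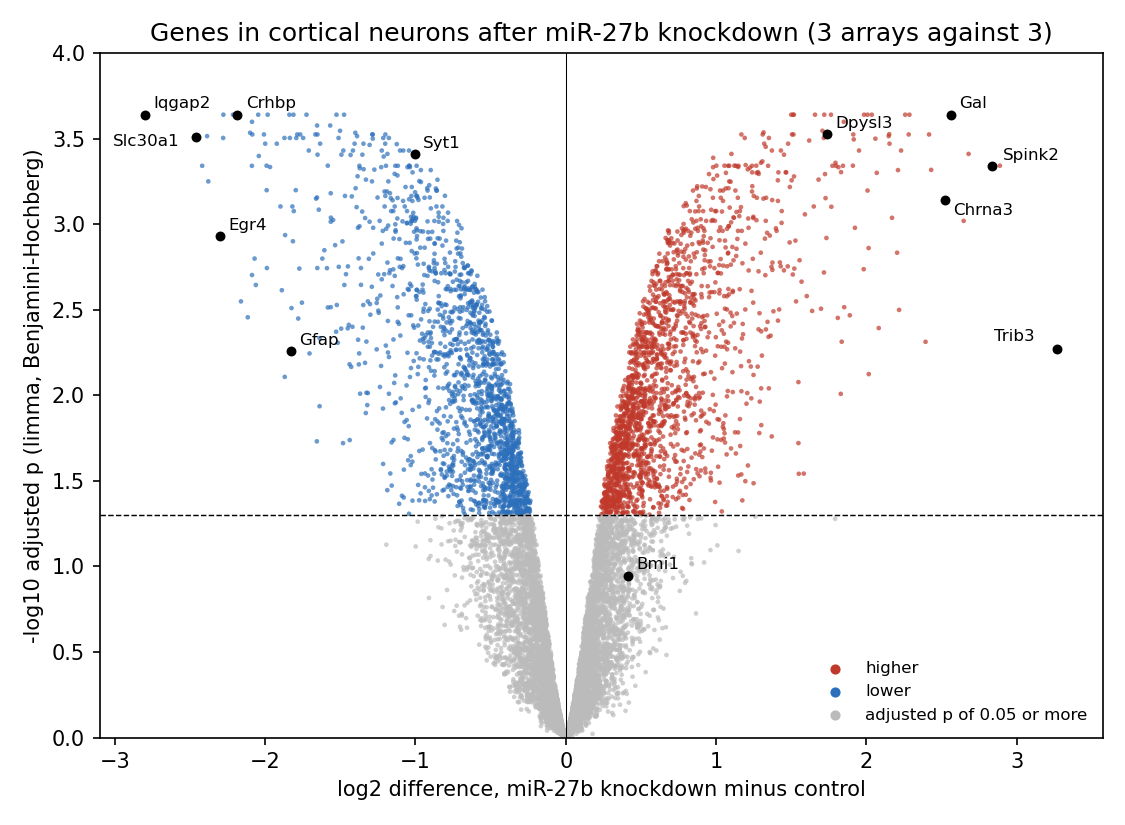
Each point is 1 of the 11183 genes tested, with the log2 difference (miR-27b knockdown minus control, 3 arrays each) on the x axis and the -log10 of the limma adjusted p on the y axis, a log scale; the dashed line marks an adjusted p of 0.05. The 1868 higher genes are red and the 1712 lower genes blue, with Trib3 farthest to the right, Iqgap2 farthest to the left and Bmi1 below the line.

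Presynaptic genes, the group the study is known to be about, lay lower as a list. Of 64 tested genes of the presynaptic list, 23 fell, 4 rose and 37 did not pass; adjusted over the list alone, 26 fell and 4 rose. The median difference was -0.18 (-0.32 with median scaling) and the list stood below other genes by camera (adjusted p = 0.00201). That call was lost with an estimated correlation (adjusted p = 0.418). Syt1, the calcium sensor of fast transmitter release, fell from a mean log2 intensity of 14.82 to 13.82 (SE of the difference 0.071, adjusted p = 0.000389). Its other detected probes, which were dimmer, differed by -1.29 and -1.79. Lin7a, a scaffold gene of synaptic junctions, differed by -1.21 (SE 0.077, adjusted p = 0.000314). Other genes of the list rose. Unc13c, which encodes a vesicle priming protein, rose by 1.84 (SE 0.14, adjusted p = 0.000456; 1.06 without background correction) and was detected on 1 of 3 control arrays, and the active zone gene Rims3 rose by 1.01 (SE 0.081, adjusted p = 0.00052).

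Postsynaptic genes fell without exception among those that passed. Of 41 tested genes, 22 fell, 0 rose and 19 did not pass (adjusted over the list alone, 25 fell and 0 rose), with a median of -0.39 and a camera adjusted p of 2.6e-07 (adjusted p = 0.418 with an estimated correlation). Camk2a, the alpha subunit gene of the abundant synaptic kinase CaMKII, differed by -1.03 (SE 0.090, adjusted p = 0.000684). Gria3, an AMPA receptor subunit gene, differed by -1.16 (SE 0.10, adjusted p = 0.000705), and Baiap2, which encodes a postsynaptic actin regulator, by -0.93 (SE 0.13, adjusted p = 0.00293). Cnksr2, a synaptic scaffold gene, had the largest fall at -1.37 (SE 0.14, adjusted p = 0.00103), but its other detected probe differed by only -0.19 (adjusted p = 0.625). Astrocyte markers moved in the same direction as both synaptic lists, with a median of -0.67.

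Voltage-gated ion channel genes leaned lower, with 10 of 30 tested genes lower, 5 higher and 15 not passing. Adjusted over the list alone, 13 were lower and 5 higher. The median was -0.38 and the camera adjusted p 0.0138 (adjusted p = 0.418 with an estimated correlation, and 0.0626 when probes had to be detected at p under 0.01 on all 6 arrays). Scn2b, a sodium channel beta subunit gene, differed by -1.22 (SE 0.085, adjusted p = 0.000371), Kcnn2, a calcium-activated potassium channel gene, by -1.15 (SE 0.15, adjusted p = 0.0023), and Kcnab1, a potassium channel beta subunit gene, by -0.70 (SE 0.11, adjusted p = 0.00486). For Kcnab1, 1 of the 3 detected probes differed by only -0.099. The calcium channel beta subunit gene Cacnb1 differed by -1.37 (SE 0.23, adjusted p = 0.00569), while its other probe differed by 0.34 (adjusted p = 0.44). Without background correction Cacnb1 differed by -0.76. Inhibitory neuron and astrocyte markers lay lower in the same arrays, with medians of -0.77 and -0.67.

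Transcripts of activity-induced immediate early genes showed the largest median shift of the 21 lists. Of 19 tested genes, 14 fell, 2 rose and 3 did not pass, with the same counts adjusted over the list alone. The 2 that rose were Crem at 0.95 and Dusp1 at 0.37 (limma adjusted p = 0.00267 and 0.0441). The median of -1.44 amounts to a 2.72-fold difference, with a camera adjusted p of 4.29e-06 (adjusted p = 0.418 with an estimated correlation). Arc, which regulates AMPA receptor traffic, differed by -2.39 (SE 0.15, adjusted p = 0.000306), and the transcription factor genes Egr4, Npas4 and Fos by -2.30, -2.09 (-1.26 without background correction) and -2.06, with adjusted p of at most 0.00227. The list medians were -1.41, -1.73 and -1.31 in the 3 preparations. Inhibitory neuron and astrocyte markers were lower too, with medians of -0.77 and -0.67.

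**Figure D2:**
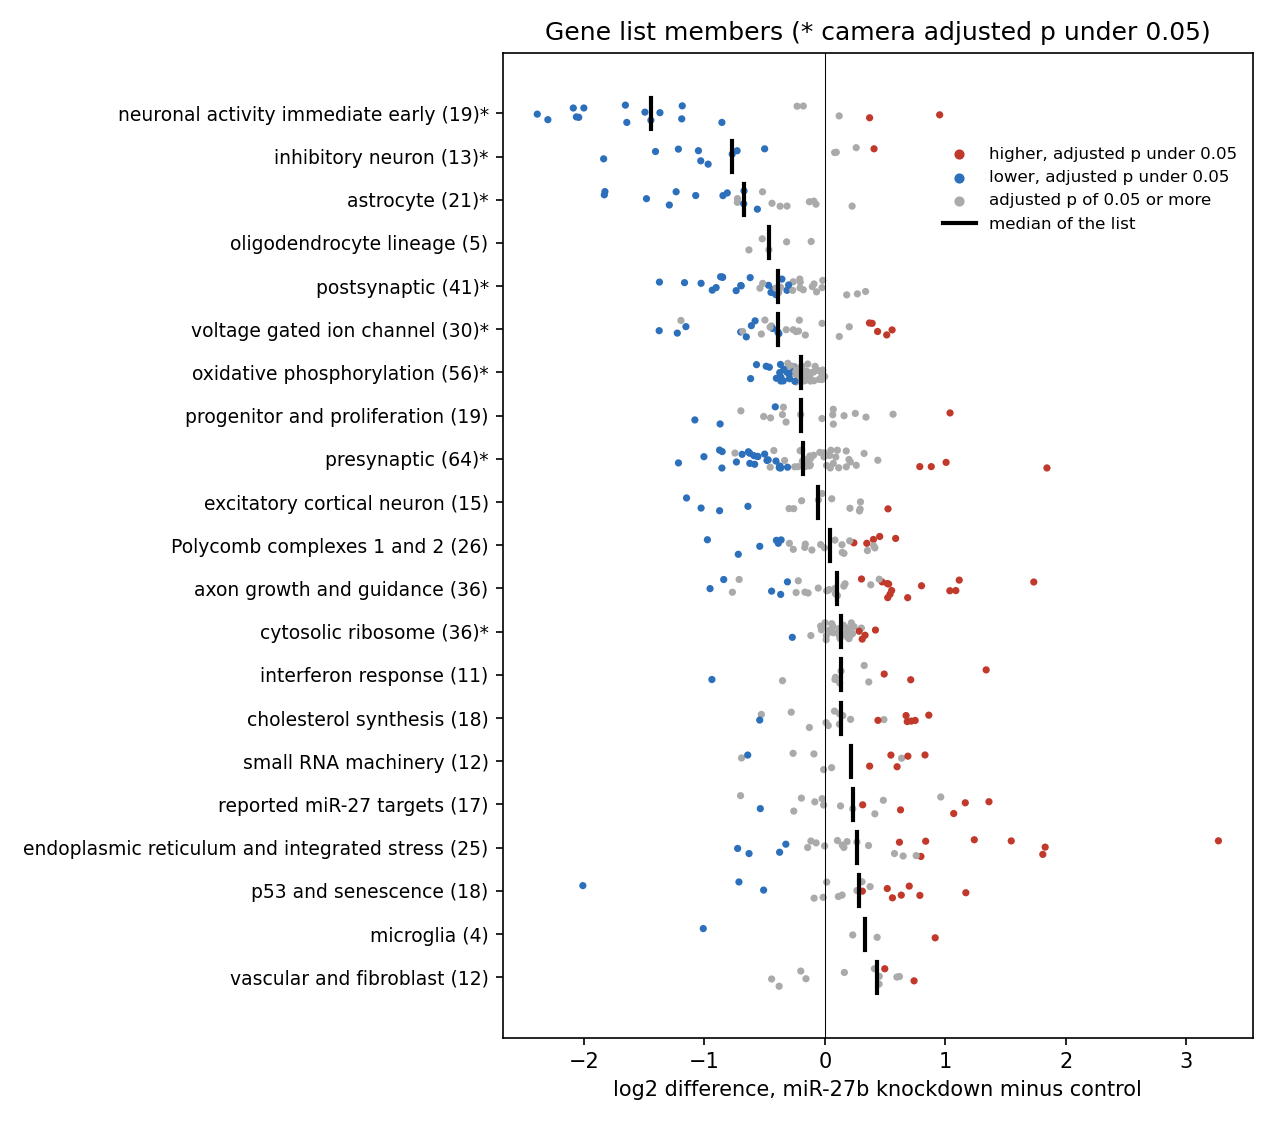
Log2 differences (miR-27b knockdown minus control, x axis) of the tested members of 21 gene lists, with the number tested in parentheses, the list median as a black bar and an asterisk at a camera adjusted p under 0.05 with the preset correlation. The activity list lies farthest to the left, with a median of -1.44, and no postsynaptic or oxidative phosphorylation gene is red.

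Inhibitory neuron markers were lower as a group, and excitatory neuron markers did not pass as a group. Of 13 tested inhibitory neuron genes, 9 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone. The median was -0.77 (-0.38 with no filter on dim probes) and the camera adjusted p 0.00556 (adjusted p = 0.418 with an estimated correlation). The neuropeptide genes Vip and Cck differed by -1.84 (SE 0.12, adjusted p = 0.000314) and -1.40 (SE 0.093, adjusted p = 0.000339). Parvalbumin (Pvalb) and the transcription factor gene Dlx6 differed by -1.22 and -1.05, with adjusted p of 0.0252 and 0.024. The gene that rose was Reln, by 0.41 (SE 0.083, limma adjusted p = 0.012). Those that did not pass were Dlx1 at 0.082, Dlx2 at 0.096 and Calb2 at 0.26. Of 15 excitatory cortical neuron genes, 4 fell, 1 rose and 10 did not pass (the same adjusted over the list alone), with a median of -0.053 (-0.19 with median scaling) and a camera adjusted p of 0.223. Astrocyte markers fell beside the inhibitory neuron markers, with a median of -0.67. The 4 excitatory neuron genes that fell were Nptx1 at -1.15, Camk2a at -1.03, the vesicular glutamate transporter gene Slc17a7 at -0.87 and Nrn1 at -0.64, with adjusted p of at most 0.017.

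Genes of energy production were lower as a list. Among 56 tested oxidative phosphorylation genes 17 fell, 0 rose and 39 did not pass, also adjusted over the list alone, and all 56 differences were below 0. The median was -0.20 (-0.36 with median scaling) and the camera adjusted p 2.95e-06 (adjusted p = 0.418 with an estimated correlation). The complex I genes Ndufa6, Ndufb9 and Ndufb7 differed by -0.62, -0.57 and -0.46, and the complex II gene Sdhc by -0.49, with adjusted p of at most 0.0152. The fall ran beside those of the inhibitory neuron (-0.77) and astrocyte markers (-0.67). Cytosolic ribosome genes lay slightly higher, with 4 of 36 higher, 1 lower and 31 not passing, a median of 0.13 and a camera adjusted p of 0.0216 (adjusted p = 0.418 with an estimated correlation). Adjusted over the list alone, limma called 0 higher and 0 lower; at an unadjusted p under 0.05, 12 were higher and 1 lower. With median scaling the ribosome median turned to -0.025, and the calls of the 4 genes that were higher (Rpl22 at 0.42, Rpl32 at 0.33, Rpl29 at 0.31 and Rps4x at 0.29) were lost. Rps4x also did not pass with the replicate block (adjusted p = 0.0637). Of 18 cholesterol synthesis genes, 6 rose, 1 fell and 11 did not pass (the same adjusted over the list alone), with a median of 0.14 (0.019 with median scaling) and a camera adjusted p of 0.0798. Those with the largest rises were Pmvk at 0.86, Cyp51 at 0.75, Tm7sf2 at 0.72 and Dhcr7 at 0.68, with adjusted p of at most 0.0112.

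Some genes of the stress responses rose strongly, but these lists did not pass as groups. In the endoplasmic reticulum and integrated stress list, 8 of 25 genes rose, 4 fell and 13 did not pass, with the same counts adjusted over the list alone. The median was 0.27 and the camera adjusted p 0.101, or 0.0158 with the replicate block. Besides Trib3, the glutathione-degrading enzyme gene Chac1 rose by 1.83 (SE 0.35, adjusted p = 0.00981), the mitochondrial folate enzyme gene Mthfd2 by 1.81 (SE 0.26, adjusted p = 0.00353) and the cationic amino acid transporter gene Slc7a3 by 1.55 (SE 0.36, adjusted p = 0.019). In the p53 and senescence list, 7 of 18 rose, 3 fell and 8 did not pass (the same adjusted over the list alone), with a median of 0.29 and a camera adjusted p of 0.183. Bbc3, which encodes the apoptosis protein PUMA, rose by 1.17 and the cell cycle inhibitor gene Cdkn1a by 0.79. Zmat3 and Sesn1, also p53 targets, differed by -2.01 and -0.71. Of 11 tested interferon response genes, 3 rose, 1 fell and 7 did not pass, against 4 and 1 adjusted over the list alone, with a median of 0.14 and a camera adjusted p of 0.183. Leaving out 1 array moved that median to between 0.15 and 0.28, and it was 0.081 without background correction. Oasl2, detected on no control array, was at least 1.39-fold higher (1.18 without background correction), Ifit2 differed by 0.71 and B2m by 0.49, the last no longer past the threshold with median scaling. Ifitm3 differed by -0.94. The adjusted p of these genes were at most 0.0345.

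Axon growth and guidance genes moved in both directions. Of 36 tested, 13 rose, 5 fell and 18 did not pass (14 and 7 adjusted over the list alone), with a median of 0.099 and a camera adjusted p of 0.122. The median was 0.0053 with median scaling and 0.21 without knockdown replicate 3. Dpysl3 and Dpysl5, which encode cytoskeletal proteins of growing axons, rose by 1.74 (SE 0.11, adjusted p = 0.000299) and 1.09 (SE 0.083, adjusted p = 0.000456). The semaphorin co-receptor gene Nrp2 rose by 1.04 (SE 0.32, adjusted p = 0.0477). The ephrin receptor gene Epha7 rose by 1.12 (SE 0.13, adjusted p = 0.00163), while its other probe differed by 0.21 (adjusted p = 0.318).

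**Figure D3:**
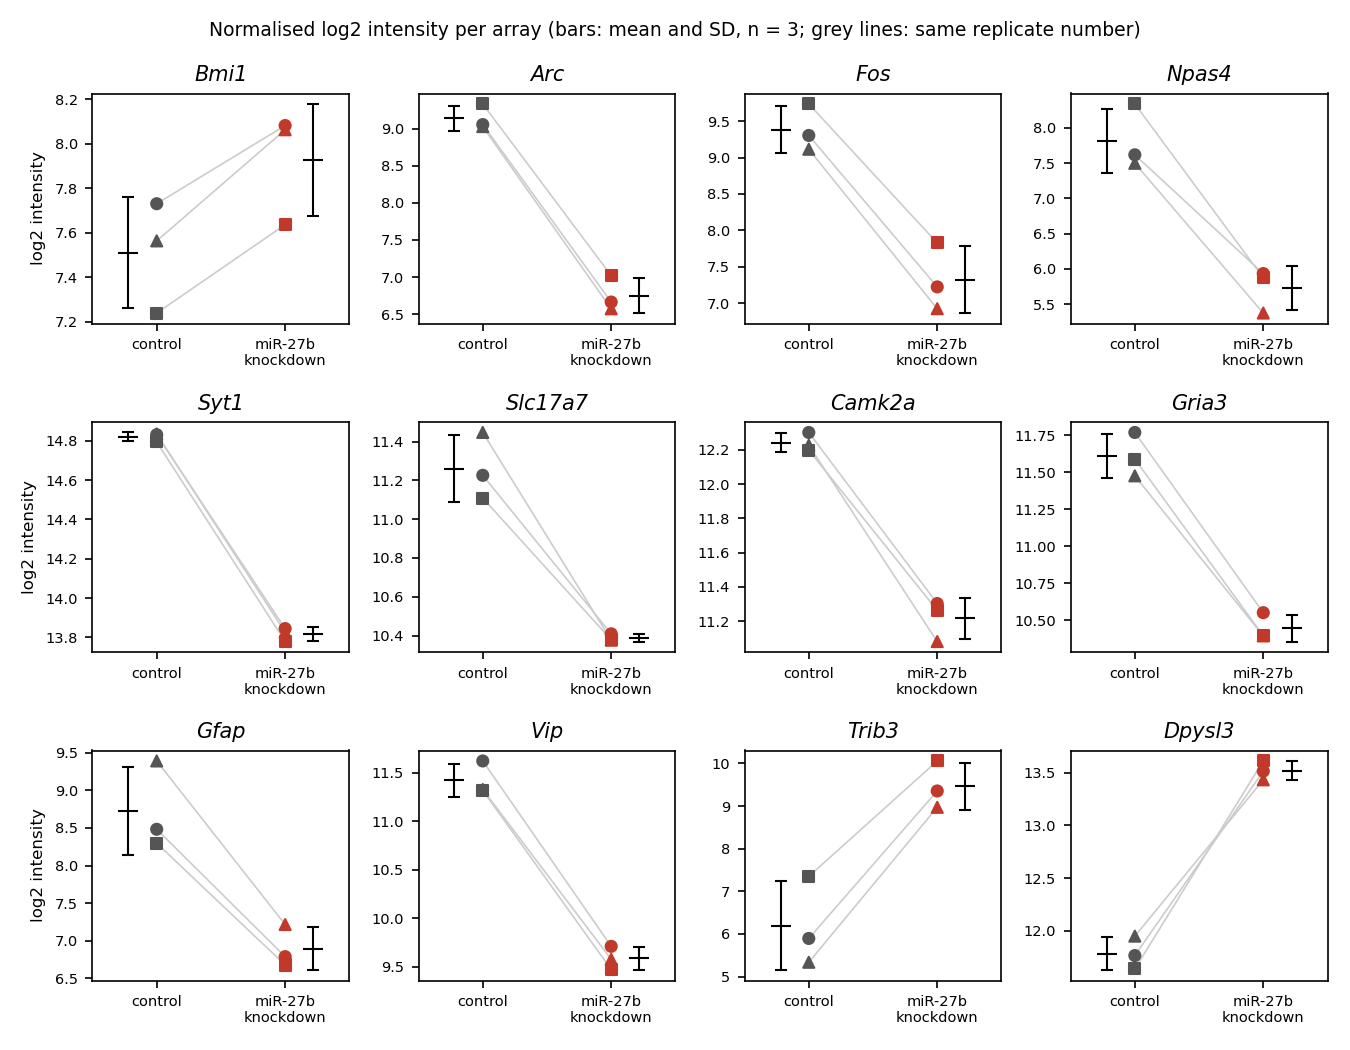
Normalised log2 intensity (y axis, scaled per gene) of 12 genes on each control array (grey) and each miR-27b knockdown array (red), with symbols and grey lines joining arrays of the same replicate number, and bars for the mean and SD (n = 3). Every gene shown except Bmi1 passed the limma test; Syt1 went from a mean of 14.82 to 13.82 and Dpysl3 from 11.79 to 13.52.

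Polycomb genes did not shift as a group. Of 26 tested members of complexes 1 and 2, 5 rose, 6 fell and 15 did not pass, with the same counts adjusted over the list alone. The median was 0.041 (-0.044 with median scaling), the mean -0.017 and the camera adjusted p 0.846, with the camera direction upward. Pcgf5, Cbx7 and Cbx8, genes of Polycomb repressive complex 1, differed by -0.97, -0.72 and -0.54, with adjusted p of at most 0.0166. Phc1, of the same complex, differed by 0.59 (adjusted p = 0.00472), a call lost with median scaling. Of 17 tested genes reported elsewhere as miR-27 targets, 5 rose, 1 fell and 11 did not pass (6 and 2 adjusted over the list alone), with a median of 0.23 and a camera adjusted p of 0.214. Cyp1b1 rose by 1.36 (0.74 without background correction), the Wnt antagonist gene Sfrp1 by 1.17, the TGF-beta receptor gene Tgfbr1 by 1.07 and the adaptor gene Gab1 by 0.63, with adjusted p of at most 0.0364. The gene that fell was Foxo1, at -0.53 (SE 0.097, limma adjusted p = 0.00815). Over all 11183 genes tested, 32% passed in either direction. Of 12 genes of the small RNA machinery, 5 rose, 1 fell and 6 did not pass (6 and 2 adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.183. Tnrc6a, which encodes a silencing complex scaffold, rose by 0.83, with 1 of its 3 detected probes at 0.17 (adjusted p = 0.70). The Dicer partner genes Prkra and Tarbp2 rose by 0.69 and 0.60. Ddx5 differed by -0.64 (adjusted p = 0.0251, or 0.0519 with the replicate block).

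Markers of cells other than neurons also differed. Of 21 tested astrocyte genes, 11 fell, 0 rose and 10 did not pass (12 and 0 adjusted over the list alone), with a median of -0.67 and a camera adjusted p of 3.91e-05 (adjusted p = 0.418 with an estimated correlation). The astrocyte filament gene Gfap differed by -1.83 (SE 0.30, adjusted p = 0.0055), while its other probe, at -1.08, did not pass (adjusted p = 0.0944). The metallothionein genes Mt2 and Mt1 differed by -1.82 (-1.13 without background correction) and -1.48, and the water channel gene Aqp4 by -1.29, with adjusted p of at most 0.00309. The 2 metallothioneins have closely related sequences, so their probes are uncertain. Of 12 vascular and fibroblast genes, 2 rose and 10 did not pass (the same adjusted over the list alone), with a median of 0.43 and a camera adjusted p of 0.208. The 2 were the basement membrane collagen genes Col4a2 at 0.74 and Col4a1 at 0.50, the latter lost with median scaling. Of 4 tested microglia genes, Fcgr3 rose by 0.92, Cd68 differed by -1.01, and the other 2 did not pass; adjusted over the list alone, 2 rose and 1 fell. The microglia median was 0.33 and the camera adjusted p 0.452. None of 5 tested oligodendrocyte lineage genes passed in limma, also adjusted over the list alone (0 higher and 1 lower at an unadjusted p under 0.05), with a median of -0.46 and a camera adjusted p of 0.183, or 0.0488 with the replicate block. The block's call was lost without pair 1 or pair 2 (camera adjusted p = 0.0664 and 0.0673). With an estimated correlation and no block the adjusted p was 0.418. Olig1 differed by -0.63 (adjusted p = 0.053, or 0.0122 with the block) and Sox8 by -0.52 (adjusted p = 0.226). Of 19 progenitor and proliferation genes, 1 rose, 3 fell and 15 did not pass (1 and 1 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 0.47. Aurka rose by 1.04, the Notch target gene Hes5 differed by -1.08, Cenpa by -0.87 and Pcna by -0.41, with adjusted p of at most 0.0419; the other probe of Hes5 did not pass (adjusted p = 0.173), nor did Pcna with median scaling.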

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

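The tests of astrocyte share, of other non-neuronal cells and of excitatory neuron share were chosen only after the values they use had been seen. Signal outside the comparisons came from 2258 detected probes with no gene symbol. Of these, 217 were higher (9.61%) and 295 lower (13.1%) after miR-27b knockdown by limma, against 14.4% and 13.6% of the 16369 detected probes with a symbol. Those with the largest differences were ILMN_1230719 at 2.08 and ILMN_2939071 at 1.86, and ILMN_1222199 at -2.42 and ILMN_1215346 at -2.37.

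The 3580 genes past the threshold are 32.0% of those tested. Of the 10 splits of the 6 arrays into groups of 3, only the real 1 gave as many; limma called 0 genes in each of the others, and at an unadjusted p under 0.05 it called 4904 genes in the real split against 158 to 424. With 10 splits no share under 0.05 can be reached, and the 3 other splits that also part every pair gave 158 to 253 genes at that unadjusted p. Each other split mixes control and knockdown arrays, so the difference between the groups adds to the spread within it. Few calls are therefore expected there, and the splits cannot weigh the real count against chance. Knockdown replicate 3, which correlates least with the rest, did not make the calls. Without it 3169 genes passed, 2865 of them among the 3580 with the same sign. With median scaling 59.4% of the called genes kept their call and sign, so quantile normalisation alone did not make most of the calls. That share is over both directions. Median scaling called 914 genes higher, against 1868, and 1360 lower, against 1712. With cyclic loess 1846 genes were higher and 1776 lower, and 97.9% of the called genes kept their call and sign. The higher calls therefore did not hang on quantile normalisation in particular. Median scaling centred each array on all 45281 probes, of which 38.6% to 42.3% were detected per array. Which scaling is right was not tested, so scaling is not excluded as the source of many higher calls. Open explanations are a lower level of miR-27b and any other difference between the 2 viruses, since the labels name a single virus per group.

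Astrocyte markers were lower, with a median of -0.67. A smaller share of astrocytes as the whole cause was predicted to lower them alike, but 10 of 21 had a 95% interval that excluded the list median. The prediction holds only for markers made by astrocytes alone and read well above background. Unequal falls therefore cannot decide whether the share was smaller. Aldh1l1, Slc1a3, Sox9 and Ntsr2 lay near or above 0, at -0.09, -0.13, -0.073 and 0.23, against -1.83 for Gfap and -1.07 for Slc1a2. The vascular and fibroblast median of 0.431 (bootstrap 95% interval over genes -0.18 to 0.55) lay above that of the astrocyte markers. It was 0.15 with no filter on dim probes. The gap between the medians argues against an equal fall of all non-neuronal cells. A smaller fall stays open, since the interval includes 0. Of the 12 vascular and fibroblast genes 4 lay below 0, among them Kdr at -0.44 and Pecam1 at -0.38, and none of the 4 passed. Oligodendrocyte lineage markers lay lower too, with a median of -0.46 (-0.027 with no filter). Their camera adjusted p was 0.183, or 0.0488 with the replicate block. The block's call was lost without pair 1 or pair 2 (adjusted p = 0.0664 and 0.0673). The 4 microglia genes had a median of 0.33 with Cd68 alone lower. A change of expression within astrocytes and a loss of astrocytes, or of glia more widely, both stay open.

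Activity-induced genes had a median of -1.44. A smaller share of excitatory neurons as the whole cause was argued against by the median of -0.0528 for excitatory neuron markers (bootstrap 95% interval -0.64 to 0.29), and it was -0.19 with median scaling and -0.13 with the mean of probes. A single preparation did not make the difference, since the highest of the 3 medians by preparation was -1.31. Lower firing in culture after miR-27b knockdown may account for it, and firing was not measured here. Health of the cultures and differences between the viruses stay open too. Inhibitory neuron and astrocyte markers also had lower medians, at -0.77 and -0.67, but fell less than the activity genes. A smaller share of other cells stays open as a part of the difference.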

How the results depend on the processing

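All 3580 called genes kept their sign under each alternative in which they were tested, except with the mean of all detected probes, where 3561 did and 4 were called in the other direction. The cause of the changes below was not tested, except that leaving out arrays leaves fewer samples. The genes higher fell from 1868 to 914 with median scaling, which moved the median of all genes from 0.0064 to -0.077; the lower genes numbered 1360. Over the omissions of 1 array, the higher genes ranged from 1242 to 1692 and the lower from 1050 to 1477, the lowest without control replicate 1. With the replicate block and a pair left out, they numbered 564 and 589 without pair 1, 698 and 703 without pair 2, and 1448 and 1308 without pair 3.

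The Bmi1 difference was positive under all 21 alternatives, from 0.28 to 0.56 over the omissions of 1 array, with adjusted p from 0.0194 to 0.275. It passed with the replicate block alone, at 0.42 (adjusted p = 0.0194). Olig1 passed under 11 and Dicer1 under 10 of 21 alternatives, and Aopep under 3 and Sox8 under 1 of 20. The block raised the counts to 1928 higher and 1829 lower, with 3270 calls shared. Among the lists and named genes it changed the calls of the endoplasmic reticulum stress and oligodendrocyte lists, Bmi1, Aopep, Olig1, Rps4x and Ddx5, and no other call. The presynaptic median of -0.18 lay between -0.23 and -0.15 over the omissions, and passed under all of 22 alternatives but the estimated correlation (adjusted p = 0.418; range over alternatives 0.000425 to 0.418).

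Among the other lists, signs turned with median scaling for ribosome (-0.025) and Polycomb genes (-0.044). The Polycomb median was also -0.018 with no filter on dim probes and with the mean of probes, -0.010 without control replicate 1 (0.071 at most over the omissions of 1 array), and -0.0084 without pair 1 under the replicate block. The progenitor median was 0.066 at a detection p under 0.01 on all 6 arrays and 0.051 without control replicate 3, against -0.40 at the lowest over the omissions. Neither list passed under any setting. Medians that moved by over 1.5 times without a new sign include endoplasmic reticulum stress at 0.47 without control replicate 2 or knockdown replicate 3, and with no filter vascular genes at 0.15, reported miR-27 targets at 0.10, oligodendrocyte genes at -0.027 and microglia at 0.015. With median scaling p53 genes were at 0.19 and small RNA genes at 0.12 (0.034 with no filter). The ribosome call was also lost with the mean of probes, without knockdown replicate 2 or 3 (adjusted p = 0.0504 and 0.0663) and without pair 2. The endoplasmic reticulum stress list passed under 9 of 22 alternatives and the cholesterol list under 5, among them without control replicate 2 (adjusted p = 0.0326 each) and with fry or an intensity trend; the latter also passed without control replicate 1 (0.0415). The axon growth list passed with an intensity trend (0.0436) and with fry (0.00837). Fry alone also passed the excitatory (0.0121), interferon (0.00599), small RNA (0.0261), miR-27 target and vascular lists (0.0473 each). Of 96 named genes past the threshold, 20 lost their call in at least 1 omission of an array, from 17 genes without control replicate 1 to 6 without knockdown replicate 3; 35 lost it in at least 1 omission of a pair (31 without pair 1), 15 under at least 1 other alternative (8 each with median scaling and with no filter) and 60 under none; no named gene changed sign, and the 24 with the largest differences passed throughout.

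Genes dim on these arrays are limited by signal over background, and 26654 probes were not tested. The miR-27 site test was not run, for lack of transcript sequences, nor were slide as a block, since the files name no slides, and the random block for lists, which camera does not take.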

Other observations

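Other genes, chosen after their values were seen, are given singly, and no list of them was tested. Of neuropeptide genes outside the lists, cortistatin (Cort) differed by -1.90 (SE 0.17, adjusted p = 0.000788), Tac1 by -1.35, Tac2 by -0.98 and Adcyap1 by -0.87, with adjusted p of at most 0.00752. Gal and Trh rose, by 2.56 and 1.01, with adjusted p of at most 0.0181. Penk at -0.30 and Pdyn at 0.66 did not pass, and Crh and Nts were not tested, being too dim. Dbp and Tef, transcription factor genes under clock control, differed by -1.38 (SE 0.16, adjusted p = 0.00158) and -1.28 (SE 0.13, adjusted p = 0.00105). The clock genes Clock, Nr1d2, Nr1d1, Per2 and Per1 differed by -1.77, -1.17, -1.14, -0.71 and -0.67, with adjusted p of at most 0.0311, while Arntl at 0.12, Cry2 at 0.079 and Ciart at -0.13 did not pass. The transcription factor genes Klf9 and Bhlhe40 differed by -1.65 and -1.51. Cry1, Per3 and Hlf were not tested, being too dim.

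The heme oxygenase gene Hmox1 rose by 2.01 (SE 0.22, adjusted p = 0.00138), Jun by 1.40 (SE 0.14, adjusted p = 0.00109) and the intermediate filament gene Prph by 2.23 (SE 0.15, adjusted p = 0.000371). Sox11 and Sox4, transcription factor genes of young neurons, rose by 1.74 (SE 0.10) and 1.31 (SE 0.095), with adjusted p of at most 0.00043. The Ras pathway genes Rasgrf1 and Map2k1 differed by -2.10 and -2.07, with adjusted p of at most 0.00159.

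Probes of the same gene sometimes parted. Of 3670 genes with more than 1 detected probe, 758 had more than 1 past the threshold, and in 23 of these the probes passed in both directions. For Mapt, which encodes the microtubule protein tau, 3 probes differed by 0.91, 0.45 and 0.58, and the other 2 by -2.07 and -2.08. For Tnik, 1 probe differed by 0.98 and the other 2 by -0.95 and -1.37. Which transcripts these probes read was not analysed here.

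A hypothesis drawn from the 13 axon growth genes that rose, though 5 fell and their list passed only with an intensity trend or fry, was that neurons given the miR-27b knockdown virus were in a less mature state. Lists of early and late neuronal genes were written for it after the values of the 21 lists had been seen but before their own were tested, leaving out genes of those lists and genes named by the rule for named genes. Of 46 early genes tested, 20 rose and 3 fell, with a median of 0.22 and a camera adjusted p of 0.00016. Sbk1 rose by 1.31 and Ina, a neuronal filament gene, by 1.16, while Rbfox1 differed by -0.90. The early list also holds Mapt, some of whose probes fell, and the late list Tef. Of 41 late genes, 14 fell and 1 rose, with a median of -0.23 and a camera adjusted p of 8.62e-05; Rgs4 differed by -1.12 and Ncdn by -0.82. The camera p-values here were adjusted over the early and late lists alone, not together with the 21 lists. Neither list passed with an estimated correlation (camera adjusted p = 0.0654 each). In settings chosen after seeing the data, the medians were 0.13 and -0.34 with median scaling and 0.21 and -0.23 without Mapt and Tef, with camera adjusted p of at most 0.00487. With an estimated correlation neither list passed there, at a camera adjusted p of 0.514 each with median scaling and 0.0755 each without Mapt and Tef. A less mature state may account for these values, and stress or lower activity of mature neurons may lower late genes as well. Inhibitory neuron and astrocyte markers also had lower medians, at -0.77 and -0.67, so a different mix of cells stays open too.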
